A study of Mus musculus with 33 samples.

How the data were processed

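Gene expression was measured in quadriceps muscle of male A17.1 mice, a transgenic model of oculopharyngeal muscular dystrophy (OPMD), and of wild-type FvB mice at 6, 18 and 26 weeks of age. Each of the 33 samples was labelled RNA on 1 Illumina Mouse v1.1 bead array, a 1-colour array on slides of up to 6 arrays. Groups, ages, slides and positions came from the labels. The labels number the samples but do not say outright that each came from a separate animal, so p-values measure the spread between these samples.

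The deposited scanner tables of 6 and 18 weeks held the mean bead intensity per probe on a linear scale, with neither background subtraction nor normalisation between arrays, per the file headers and the values. They held no detection p-values, no marked control probes and no gene names. The deposited value table of all 33 arrays held log2 values. Set against the scanner tables, each of its columns at 6 and 18 weeks had a rank correlation of 1 with the same array and slopes between 0.938 and 1.06, so no background subtraction was visible. Sorted values of the arrays of one age differed from their mean by at most 0.0430 (log2) at 6 weeks, 0.0540 at 18 weeks and 0.00141 at 26 weeks. The medians were 6.55 at 6 weeks, 6.09 at 18 weeks and 6.58 at 26 weeks, so the arrays had been quantile normalised within each age and not across ages. The submitters' processing notes name limma with no version, and the scanner software is not given in the sources used here. Scanner values of 26 weeks were not analysed here, and the value table was used for that age.

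Each scanner table had 48286 lines. Repeated probe IDs, 46 at 6 weeks and 32 at 18 weeks, held identical values and were used once. The value table left out 1597 of the IDs at 6 weeks and 1611 at 18 weeks. After removal of those brighter than the median plus 3 median absolute deviations, 1522 and 1551 of these served as the background set. The files do not mark them as controls, so this use is an assumption. Their signals gave the detection p-value of each probe on each array and the negative controls for the normexp background correction of limma's neqc procedure, with an offset of 16 and quantile normalisation. Probes with a detection p under 0.01 on at least 4 arrays at 6 weeks (17832 probes) or 5 arrays at 18 weeks (13918 probes) were tested. At 26 weeks the 18030 probes kept at either younger age were tested.

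OPMD was compared with wild type within each age with limma (version 3.58.1, R 4.3.3), using empirical Bayes moderation with a mean-variance trend. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. Differences between ages in the OPMD minus wild-type difference were tested on the value table in one limma fit with 6 group means. Because the ages were normalised separately, levels of one group were not compared between ages, and the planned test of age in wild type, which required joint normalisation, was not run. Each slide held both genotypes but a single age, so age and slide cannot be told apart. The slide was tried as a block, and each slide was also fitted alone.

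Wild-type replicates 15 and 16 at 26 weeks were much closer to each other than any other pair of one group. The SD of their log2 difference was 0.0919, and the next lowest of all pairs was 0.189. Bead noise is not given in the files, so it could not be shown that this lies within technical noise. The arrays were averaged and counted as 1 sample, named replicate 15, leaving 32 samples. That choice departed from the planned use of all arrays and was made after the data had been seen, including the count with the arrays kept apart. Both counts are given.

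The files do not pair probe IDs with gene names, and no table used here pairs them. The planned tests of 34 gene lists, of Pabpn1 probes and of named genes were therefore not run. Probes named in the text instead followed a rule set after the files had been seen and before the fits by age were run. Among probes called at all 3 ages in one direction, the 2 per direction with the largest smallest absolute log2 fold change were named. Where a probe was detected on no array of a group, the fold is given as a bound. The bound sets the bright group's mean against the mean of, per array, the higher of the lowest detected probe and the probe itself.

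The fits were tested on simulated arrays with the real probe means and a pooled spread per probe, in which 200 probes were changed. Noise was independent between probes, with equal spread in all groups and no slide effect. Far fewer probes were changed than were called in the data, so the rates below may not hold for the real arrays. Of the probes changed 2-fold, 89.6% were recovered at 6 weeks (17832 probes), 86.6% at 18 weeks (13918 probes) and 100% at 26 weeks (18030 probes). Of those changed 1.5-fold, 52.2%, 58.2% and 76.1% were recovered. False calls numbered 8, 14 and 9. In the fit that compares ages (18030 probes), 92.5% of probes whose difference changed 2-fold were recovered for 26 against 6 weeks and 92.5% for 26 against 18 weeks. The number of arrays limits the precision.

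The alternatives covered background correction, normalisation, the filter on dim probes, the slide, the replicate number, array weights, the source of the values, a fold threshold and leaving out each sample. Most were fixed before the data were examined. Those chosen afterwards were the arrays kept apart, normexp on the value table and normalisation of the value table over all ages.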

Results

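Oculopharyngeal muscular dystrophy is an inherited muscle disease caused by an expanded PABPN1, a nuclear protein that binds poly(A) tails. The A17.1 mouse carries such an expanded form, and the study characterised its muscle at the molecular level. Quadriceps RNA was profiled at 6 weeks (6 OPMD and 4 wild-type arrays), 18 weeks (5 and 6 arrays) and 26 weeks (6 and 6 arrays). At 26 weeks, 2 wild-type arrays were nearly alike and were counted as 1 sample, giving 6 against 5. The median probe signal at 6 weeks was 93.3 ± 8.44 (SD, n = 6) in OPMD and 93.8 ± 4.64 (SD, n = 4) in wild type. At 18 weeks it was 69.5 ± 6.43 (SD, n = 5) and 67.3 ± 5.10 (SD, n = 6). More probes were detected per array at 6 weeks, 16421 to 17818, than at 18 weeks, 12804 to 14249. The files do not pair probes with genes, so results are given for probes.

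The first question was which transcripts differ between OPMD and wild-type muscle at each age. At 6 weeks, 7091 of 17832 probes (39.8%) differed, with 3600 higher and 3491 lower in OPMD. The change was at least 2-fold for 1030 higher and 721 lower probes, and at least 4-fold for 198 and 121. The median log2 fold change was 0.68 among the higher probes and -0.59 among the lower. The values of the groups did not overlap in 5657 of all tested probes (31.7%), which chance gives for 0.952%. Calls are from limma with Benjamini-Hochberg adjustment. With the slide as a block 7159 probes were called, and within slide 1 alone 5359. Slide 2 held WT_6wk replicate 4 as its only wild-type array, so its count is not given. With arrays scaled only to the same median, 3718 probes were higher and 2613 lower, so the near-equal numbers depended on the normalisation.

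At 18 weeks, 3986 of 13918 probes (28.6%) differed, with 1970 higher and 2016 lower in OPMD. Changes of at least 2-fold were found for 630 higher and 582 lower probes, and of at least 4-fold for 116 and 115. The median log2 fold change was 0.75 among the higher probes and -0.72 among the lower. Groups did not overlap in 2690 of all tested probes (19.3%), against 0.433% by chance. With the slide as a block 4919 probes were called, and within each slide alone 2817 and 4044. With arrays scaled only to the same median, 2044 probes were higher and 1458 lower, which turned the balance between higher and lower probes.

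At 26 weeks, 4457 of 18030 probes (24.7%) differed, with 2520 higher and 1937 lower in OPMD. Changes of at least 2-fold were found for 356 higher and 286 lower probes, and of at least 4-fold for 33 and 45. The median log2 fold change was 0.49 among the higher probes and -0.53 among the lower. Groups did not overlap in 3039 of all tested probes (16.9%), against 0.433% by chance. With the nearly alike arrays kept apart 4899 probes were called, with the slide as a block 4647, and within each slide alone 4390 and 932. Among the 6010 dimmest probes tested, 648 were higher and 192 lower. Among the 6010 of middle level the numbers were 778 and 575, and among the 6010 brightest 1094 and 1170. In the fit with 6 group means, 2626 probes were higher and 2472 lower. The excess of higher probes at 26 weeks therefore depended on signal level and on the fit. Fold sizes at this age came from the value table, with no background correction added here. Whether the submitters had corrected the 26-week values could not be checked. On the value table the 2-fold counts were 534 and 404 at 6 weeks and 321 and 299 at 18 weeks.

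**Figure D1:**
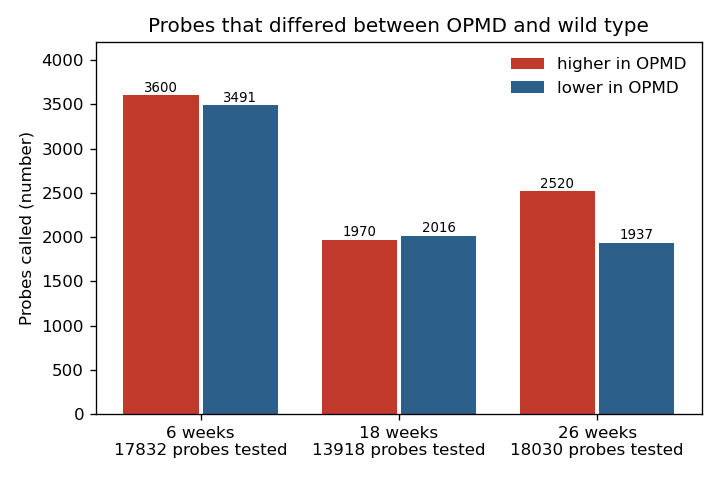
Number of probes that differed between OPMD and wild type at each age (y axis, probes called with limma at a Benjamini-Hochberg adjusted p under 0.05), with red bars for probes higher and blue bars for probes lower in OPMD. At 6 weeks 3600 were higher and 3491 lower, and at 26 weeks 2520 and 1937; the number tested differed between ages.

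Some transcripts were above background in one genotype and not in the other. At 6 weeks, 261 probes were detected on every OPMD array and on no wild-type array, and 70 showed the reverse. At 18 weeks the numbers were 182 and 79. Of these probes, 35 were detected only in OPMD at both ages, and 14 only in wild type at both. OPMD arrays detected more probes in general, 17275 ± 393 (SD, n = 6) against 16617 ± 150 (SD, n = 4) at 6 weeks and 13782 ± 445 (SD, n = 5) against 13261 ± 280 (SD, n = 6) at 18 weeks. Over all 210 splits of the 6-week arrays the highest other total was 27 probes, against 331 for the genotypes. Over the 462 splits at 18 weeks it was 82, against 261.

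The next question was whether the same probes differed at each age. The direction of change was largely shared. Of 13720 probes tested at every age, 7016 were called at 1 age or more and 2430 were called at all 3 ages in one direction, 1199 higher and 1231 lower in OPMD, where independent lists would share 58.0 and 58.2. Only 2 probes were called at all 3 ages with mixed directions. Probes called at both 6 and 18 weeks changed in the same direction in 99.8% of cases (1572 higher and 1670 lower, against 387 and 435 for independent lists). For 6 and 26 weeks the share was 99.5% (1578 and 1475, against 404 and 397), and for 18 and 26 weeks it was 99.96% (1307 and 1326, against 295 and 270). The ages shared no control samples. Across probes, which are not independent replicates, the Pearson correlation of log2 fold changes was 0.887 ± 0.0255 (jackknife SE over samples) for 6 and 18 weeks, 0.812 ± 0.0217 for 6 and 26 weeks, and 0.860 ± 0.0314 for 18 and 26 weeks. The Spearman correlations were 0.799, 0.735 and 0.743. Fold changes of 26 weeks had no background correction added here, unlike those of the younger ages. With the value table used at every age, the Pearson correlations were 0.882, 0.846 and 0.879 in the same order, so part of the lower agreement with 26 weeks came from the processing.

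**Figure D2:**
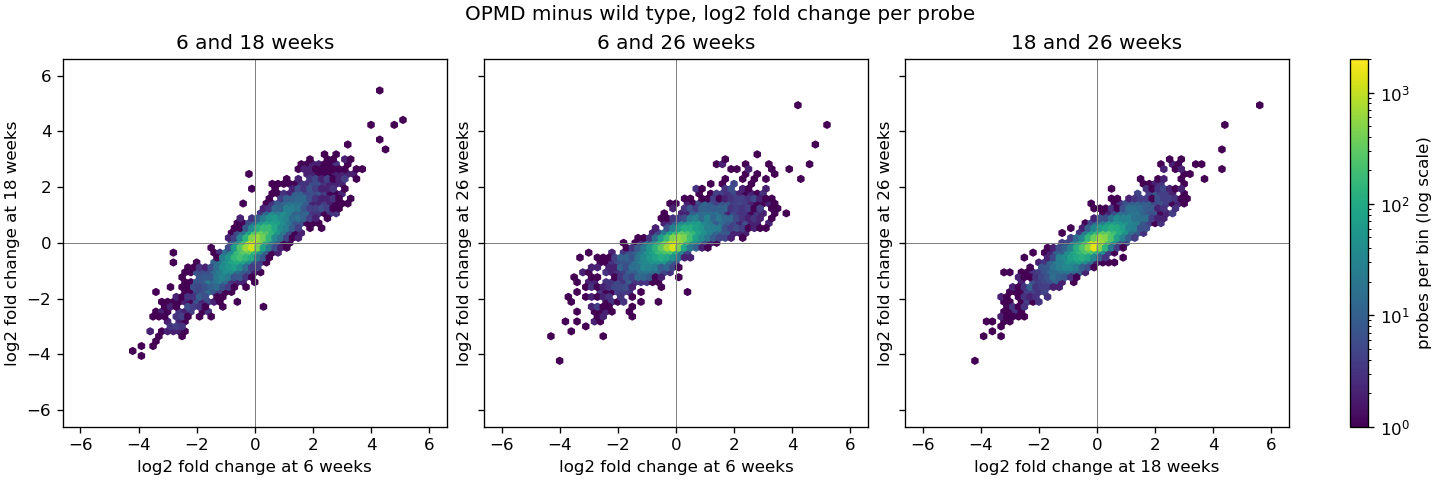
Log2 fold change of OPMD over wild type per probe at one age (x axis) against another (y axis) for 13720 probes, with colour for the number of probes per bin on a log scale. Most probes lie along a rising line, with Pearson correlations of 0.887, 0.812 and 0.860 from left to right. Fold changes of 26 weeks were not background corrected here, unlike those of the younger ages.

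Probe 1230746 was among the largest rises. At 6 weeks its log2 value was 8.92 ± 0.65 (SD, n = 6) in OPMD. It was above background on all 6 OPMD arrays and on 0 of the 4 wild-type arrays, so it was at least 10.3-fold higher after background correction (limma, Benjamini-Hochberg adjusted p = 4.2e-08). At 18 weeks it was detected on all 5 OPMD and 0 of the 6 wild-type arrays, and was at least 23.7-fold higher after background correction (limma, Benjamini-Hochberg adjusted p = 4.8e-10). These bounds rest on the background set, and without background correction the log2 fold change was 2.54 at 6 weeks and 3.78 at 18 weeks. At 26 weeks, where no background correction was added here, its log2 fold change was 4.91 ± 0.14 (SE, n = 6 and 5, limma, Benjamini-Hochberg adjusted p = 3.8e-12). Detection at 26 weeks is unknown, and the wild-type mean of 6.23 lay below the median of all probes, 6.58, so this value is not a measured fold if wild type was at background there too. Probe 3800537 rose by a log2 fold change of 5.18 ± 0.28 (SE) at 6 weeks, 4.43 ± 0.21 at 18 weeks and 4.21 ± 0.18 at 26 weeks, with limma Benjamini-Hochberg adjusted p-values of 6.9e-09, 6.6e-09 and 2.1e-10.

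Among the largest falls, probe 460332 had log2 fold changes of -3.96 ± 0.29 (SE) at 6 weeks, -4.11 ± 0.17 at 18 weeks and -4.28 ± 0.11 at 26 weeks (limma, Benjamini-Hochberg adjusted p = 1.1e-07, 2.8e-09 and 1.8e-12). At 6 weeks its log2 value was 8.89 ± 0.71 (SD, n = 6) in OPMD and 12.86 ± 0.06 (SD, n = 4) in wild type. Probe 101850110 had log2 fold changes of -4.26 ± 0.23 (SE) at 6 weeks, -3.81 ± 0.13 at 18 weeks and -3.41 ± 0.11 at 26 weeks (limma, Benjamini-Hochberg adjusted p = 6.8e-09, 5e-10 and 1.3e-11). Both stayed above background on all OPMD arrays at 6 and 18 weeks. Only the values of 6 and 18 weeks were background corrected here, so their fold changes cannot be taken as on one scale with those of 26 weeks. In the value table, with no background correction added here, the log2 fold changes at 6, 18 and 26 weeks were -3.77, -3.65 and -4.28 for probe 460332, -3.59, -2.94 and -3.41 for probe 101850110, and 4.63, 3.67 and 4.21 for probe 3800537.

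**Figure D3:**
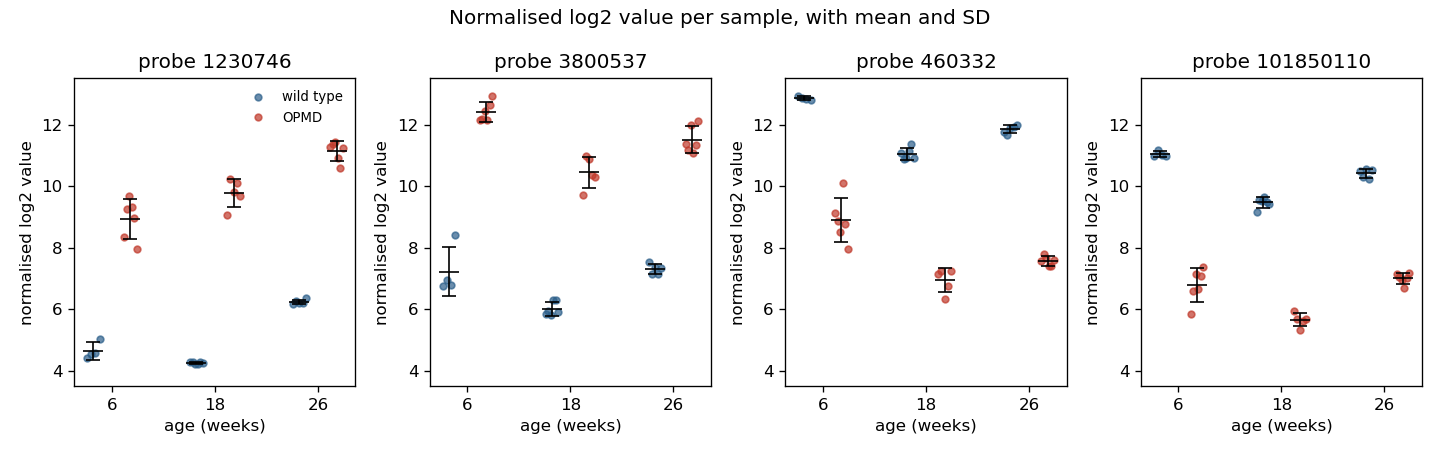
Normalised log2 value (y axis) of the 4 named probes at each age (x axis, weeks), with one point per sample, blue for wild type and red for OPMD, and bars for the mean and SD. In each panel the genotypes do not overlap at any age. Ages were normalised separately and 26 weeks was not background corrected here, so levels are comparable only within an age.

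The last question was whether the OPMD minus wild-type difference itself changed with age. In a limma fit of the value table with Benjamini-Hochberg adjustment, the difference at 18 weeks departed from that at 6 weeks for 906 of 18030 probes. Of these, 742 had the same sign at both ages and were larger at 6 weeks, 34 were larger at 18 weeks, and 130 differed in sign, of which 8 were called in opposite directions at both ages. Between 26 and 6 weeks 1321 probes departed, with 925 larger at 6 weeks, 77 larger at 26 weeks and 319 of different sign, of which 21 were called in opposite directions at both ages. Between 26 and 18 weeks 24 departed, and 147 with the slide as a fixed block, 68 as a random block and 12 to 41 with each sample left out in turn. These numbers also depended on the normalisation of the ages. With the value table normalised over all ages, a choice made afterwards, they were 107, 321 and 76. Of the 107 probes 48 were larger at 6 weeks and 37 larger at 18 weeks. Of the 321 probes 107 were larger at 6 weeks and 127 larger at 26 weeks. With the scanner tables of 6 and 18 weeks normalised together, as planned beforehand, 231 probes departed between 18 and 6 weeks.

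The size of the difference at an older relative to a younger age was taken as a slope over probes called at the third age. It was the slope of the major axis of their log2 fold changes at both ages. This slope also depends on the noise at each age, so it need not equal the ratio of the true differences. At 18 relative to 6 weeks it was 0.849 (95% jackknife interval 0.804 to 0.896). At 26 relative to 6 weeks it was 0.858 (0.822 to 0.896), and at 26 relative to 18 weeks 0.996 (0.949 to 1.05). With normexp background correction of the value table the ratios to 6 weeks were 0.819 (0.775 to 0.865) and 0.895 (0.857 to 0.935), and that of 26 to 18 weeks was 1.08 (1.02 to 1.13). With all ages normalised together the ratios to 6 weeks were 1.07 (1.01 to 1.12) and 1.09 (1.04 to 1.13) and that of 26 to 18 weeks 1.01 (0.964 to 1.06), so the direction against 6 weeks turned with joint normalisation.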

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

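The test of joint normalisation, the draws on jointly normalised values, the check with normexp on the value table and the test of slide differences in spread were chosen only after the results they bear on had been seen.

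The difference between OPMD and wild type departed from that at 6 weeks for 906 probes at 18 weeks and 1321 at 26 weeks, and 24 probes departed between 26 and 18 weeks. With genotypes permuted within ages, 2 of 100 draws gave as many probes as 906 (highest other 1343), 1 of 100 as many as 1321 (highest other 1291) and 1 of 100 as many as 24 (highest other 1), each counting the real one. Even so, a permuted draw exceeded the real count between 18 and 6 weeks. In the draws that gave 1343 and 1291, all 10 samples of 6 weeks kept their genotype and 7 of 11 older samples did, so the real 6-week difference entered them. With all ages normalised together the real counts were 107, 321 and 76 and the highest other draws 76, 98 and 546. There 1, 1 and 2 of 100 draws were as large, so a permuted draw far exceeded the count between 26 and 18 weeks. Permuting genotypes breaks up the OPMD minus wild-type difference that the ages share. None of these draws therefore tests whether a shared difference was of equal size at each age, and no conclusion on chance is drawn from them.

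For probe 1230746 the fit gave a difference of 1.38 (log2) between 18 and 6 weeks and 2.14 between 26 and 6 weeks, and 2.45 and 3.26 with all ages normalised together. In wild type the probe was not detected above background on any array at 6 and 18 weeks. Background therefore weighs on these sizes and no change with age is read from them. For probe 101850110 the difference between 18 and 6 weeks was 0.66 (limma, Benjamini-Hochberg adjusted p = 0.016). The call was lost with scanner tables normalised together (0.03, limma adjusted p = 0.99 after Benjamini-Hochberg) and with all ages normalised together (-3.76e-05, limma adjusted p = 1 after Benjamini-Hochberg).

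For the differences between 6 and 26 weeks, compression of fold changes by unsubtracted background and array brightness was weighed first. When the 26-week deviations were rescaled to the 6-week size by a common factor, 73.7% of the 1321 probes stayed called, over the limit of 50% set beforehand. This argues against compression by a common factor as the whole cause. Normexp background correction of the value table, with an offset of 50, kept 1145 probes (86.7%). Neither check decides on background compression that differs with signal level. At 6 weeks such normexp on scanner values moved probe 1230746 only from 2.54 to 2.90 (log2), against 4.28 in the main fit. Normalising all ages to one distribution kept 18.6% (246 probes), and the median absolute difference of the 1321 probes fell from 0.53 to 0.30 (log2) while its median SE went from 0.12 to 0.13. A level-dependent difference in signal scale between the separately normalised ages, of which background can be part, may therefore contribute. A change with age stays open beside it, since the joint normalisation was chosen after its count had been seen. No slide held arrays of different ages, so a change with age cannot be told apart from a difference between the slides. Genotypes also sat at partly other positions at 26 weeks than at 6 weeks, so a position effect could enter these differences too.

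In 18-week arrays the deviation of WT_18wk replicate 9 from the other arrays of its group was 0.233, apart from the other 5 on the low side. The log2 value of probe 3800537 in WT_6wk replicate 4 was 8.41, apart from the other 3 wild-type values on the high side. Chance sets apart about 1 in 20 groups, and 2 of 38 groups tested were set apart, against 1.9 by chance. Among the IDs left out of the value table, which were not otherwise tested, 2 differed between genotypes at 6 weeks and 1 at 18 weeks (limma, Benjamini-Hochberg), by at most 0.27 (log2).

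Array position was tied to genotype, with positions A, C and E holding OPMD at 6 and 18 weeks and A, B and C at 26 weeks. Positions B and E therefore exchanged genotype between 26 weeks and the younger ages, so a position effect would keep the sign of B minus E, and a genotype effect would turn it. Over 7016 called probes the correlation of B minus E between slides of 26 weeks and of younger ages had a median of -0.784 (8 pairs of slides, -0.815 to -0.726). This argues against array position as the whole cause, and the genotype remains a hypothesis for the differences at each age.

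Chance is an unlikely source of the counts at each age. Only 1 of 100 splits, the real one, gave as many probes at 6 weeks (7091, highest other 26), 18 weeks (3986, highest other 2196) and 26 weeks (4457, highest other 2794). No share below 1 of 100 could be reached with these draws. The highest other splits at 18 and 26 weeks held 0 of 5 and 1 of 6 OPMD samples in the group taken as OPMD, and so nearly mirrored the genotypes. A split by slide called 0, 1509 and 2 probes at 6, 18 and 26 weeks, so the slides differed at 18 weeks.

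OPMD arrays varied more than wild-type arrays at 18 and 26 weeks, and the difference at 6 weeks did not pass the test. The mean deviation (log2) from the other arrays of the group at 18 weeks was 0.354 ± 0.0486 (SD, n = 5) in OPMD and 0.263 ± 0.0155 (SD, n = 6) in wild type (two-sided exact permutation p = 0.00216, adjusted 0.00648 over 3 ages). At 26 weeks it was 0.302 and 0.185 (exact permutation p = 0.00866, adjusted 0.013), and at 6 weeks 0.224 and 0.155 (exact permutation p = 0.0762, adjusted 0.0762). Each deviation was taken from the other arrays of the same group, so deviations within a group are not independent. These p-values may therefore overstate the evidence. Slide differences are argued against, since with slide means taken out the SD ratio was 1.51 or more at every age, and so is a varying extent of the shared OPMD response as the main source, since 0.567%, 0.601% and 0.175% of the within-OPMD variance at 6, 18 and 26 weeks lay on the axis of another age. These shares were above those of 95% of random axes (0.0502%, 0.108% and 0.0943%), and within wild type they were 0.999%, 0.202% and 0.290%, so a small part is not excluded, while tissue sampling, RNA quality and variable disease between animals were not tested and stay open.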

How the results depend on the processing

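All alternatives kept the direction of every probe called in both fits at each age, and the 4 named probes kept direction and call in all 282 alternative values. These 4 were chosen for large changes called at all 3 ages, so their stability says little about other probes. Where detection on every array was required, probe 1230746 was dropped at 6 and 18 weeks and gave no value. The 282 include the fit within slide 2 alone, which is not interpreted. Counts moved beyond 1.5 times as follows, and the cause was not tested unless given. At 1.5-fold or more, 3842, 2634 and 1836 probes were called at 6, 18 and 26 weeks, by construction. Within slide 2 alone 2875 were called at 6 weeks, with WT_6wk replicate 4 as the only wild-type array, so this count is listed and not interpreted. Within slide 6 alone 932 were called at 26 weeks, against 4390 within slide 5 alone. Slide 6 had fewer samples than slide 5 only through the averaging of the nearly alike arrays. The cause of its lower count was not tested.

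Between 18 and 6 weeks, 231 probes were called with scanner tables normalised together and 107 with the value table normalised over all ages. Between 26 and 6 weeks, 2189 were called with array weights and 321 with all ages normalised together. Between 26 and 18 weeks the number was 68 with the slide as a random block, 147 as a fixed block, 15 with no filter, 50 with array weights, 41 with 33 arrays, 55 with normexp on the value table and 76 with all ages normalised together. The 18 minus 6 difference of probe 101850110 was 0.03 with scanner tables together and -3.76e-05 with all ages together. The 33 arrays, normexp on the value table and all ages together were chosen after seeing the data. The correlation between 6 and 26 weeks was 0.846 from the value table and 0.739 with no filter, and between 6 and 18 weeks 0.819 with no filter.

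Leaving out each sample gave 6096 to 7434 probes at 6 weeks, 3565 to 3988 at 18 weeks and 3751 to 5092 at 26 weeks. The age differences ranged from 701 to 970 (18 and 6 weeks), 998 to 1435 (26 and 6 weeks) and 12 to 41 (26 and 18 weeks). The last was 37 without OPMD_18wk replicate 7, 15 without WT_18wk replicate 8, 12 without WT_26wk replicate 12, 39 without OPMD_26wk replicate 15 and 41 without OPMD_26wk replicate 17. Probes called at all 3 ages numbered 2236 to 2475. The correlations were 0.871 to 0.889 (6 and 18 weeks), 0.803 to 0.818 (6 and 26 weeks) and 0.843 to 0.865 (18 and 26 weeks).

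The replicate number as a block gave 6503, 3349 and 3479 calls at 6, 18 and 26 weeks. No clear pairing by number was seen, since 7 of 12 same-number pairs correlated at 0.1 or less and 4 of 12 correlated best with their own number. The correlations ran from -0.387 to 0.574, and so few pairs cannot exclude a pairing. The planned gene list, Pabpn1 and wild-type age alternatives were not run, as probes have no gene names here and ages were normalised separately. Signal over background limits dim probes, more at 18 than at 6 weeks, and is unknown at 26 weeks.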
